A study of Rattus norvegicus with 6 samples.

How the data were processed

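In situ transcript detection (Xenium, 10x Genomics) had been run on 6 rat kidney sections, 1 for each combination of 2 genotypes and 3 conditions. The genotypes were wild type and Brca1(L63X/+), in which 1 Brca1 allele carries the L63X change. The conditions were untreated control and kidneys taken 1 week or 3 weeks into intraperitoneal ferric nitrilotriacetate (Fe-NTA), an iron chelate that injures the proximal tubule. Per the labels, kidneys were fixed in 10% formalin for 48 h, embedded in paraffin and cut at 5 µm. The deposited matrices hold counts, as the authors' pipeline produced them: whole numbers of decoded transcripts per feature and segmented cell, with no scaling. The segmentation and decoding software and any quality threshold on transcripts are not given in the sources used here. Each matrix holds 541 features: 50 panel genes, 20 negative control probes, 41 negative control codewords and 430 unassigned codewords. All 50 symbols had an entry in the RefSeq gene table, which was used for names only. Positions of cells and tissue images were not used here.

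Cells with fewer than 10 panel counts were left out, which removed 0.281% to 2.19% of the cells of a section. Counts were summed over the kept cells of each section and given as counts per 10000 panel counts. A gene counted as above background in a section when its count was at least 3 times the mean of the 61 negative control features. With 1 section per genotype and condition, a pair of sections was compared by size only: a gene was called higher or lower at 2-fold or more, if above background in the higher section, with at least 100 counts over both sections and the same sign under every scaling tried. Intervals of counts and folds are exact 95% Poisson intervals, and intervals of cell shares are 95% Clopper-Pearson intervals. Both cover counting error only and say nothing about differences between animals.

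Fe-NTA and genotype effects were fitted over the 6 sections with an additive model, genotype plus condition, using the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Benjamini-Hochberg adjustment ran over the 50 genes of each contrast with a threshold of 0.05. Library size was the section total, and 2 residual degrees of freedom were left. Every edgeR fit here also borrowed spread across genes. Its p-values and standard errors therefore do not rest on a gene's own residual degrees of freedom alone. Because each group had 1 section, the residual spread holds the genotype-by-condition differences together with differences between animals and sections. The genotype-by-condition difference was not tested week by week, since a model with both terms leaves no residual degrees of freedom. A term for genotype by Fe-NTA with both weeks joined, which leaves 1, was added after the data were seen. A gene was listed as opposite between genotypes when it was at least 1.5-fold higher in one genotype and at least 1.5-fold lower in the other, with those signs under every scaling.

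Cells of all sections were clustered together on 16 panel genes that were cell type markers and on no functional list. Counts were scaled to the median total of these genes, log-transformed and reduced to 10 principal components. Leiden clustering (leidenalg 0.10.2) ran on 8000 cells per section with 100 neighbours and a resolution of 0.4, and the remaining cells went to the nearest cluster mean. The neighbour number and resolution were set after a first run gave too many clusters, from the clusters alone and not from their shares in the groups. This gave 13 clusters, and 45865 kept cells without a count of the 16 genes were set apart as cluster 0. Clusters 2 and 3 were joined as proximal tubule-like and cluster 9 was called podocyte-like, since 3 markers of those types stood among their leading genes; the others stay numbered with their leading genes. Assignment to the nearest mean gave 80.6% of the subsample its Leiden cluster. Logit shares were fitted with limma 3.58.1 in the same additive design, adjusted over the 13 sets of cells. Sums within a class were fitted with edgeR as above, and the 16 clustering genes were not reported there.

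Proximal tubule-like cells with at least 2 counts of Lcn2, the injury marker of the panel, were compared with the other proximal tubule-like cells of the same section. Each cell was thinned to 20 counts, a depth that at least 91.3% of the kept cells of every section reached, and Lcn2 was left out. An exact two-sided sign test over the 6 sections was applied to 49 genes, with a smallest possible p of 0.031, and adjusted by Benjamini-Hochberg.

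Gene lists were fixed before the data were examined. They covered ferroptosis defence (2 panel members), ferroptosis promotion or lipid peroxidation (2), iron handling (9), tubular injury and repair (2), cell cycle (1), DNA damage response with p53 and cell cycle arrest (8), mitochondria (1), carcinogenesis (8) and inflammation and fibrosis (1). A gene may stand on several lists, and the authors chose the panel for such topics, so no enrichment was computed. The genes named in the text were those with the up to 10 highest and 10 lowest ratios among genes called by size in each comparison, every member of the ferroptosis and iron lists, Brca1, Lcn2, Mki67 and Cdkn1a, the leading genes of clusters, and genes opposite between genotypes. This rule was also fixed before the data were examined. Some genes that the rule takes, and a set test on cells without an Mki67 count, are not reported here. Other named genes are members of a list or of a small count and were chosen after their values were seen.

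The alternatives tried were transcripts per kept cell, TMM factors, DESeq2 size factors, a denominator without the 3 genes of highest total, other cell filters, subtraction of the background, the same cluster mix in every section, size limits of 1.5-fold and 3-fold, DESeq2 1.42.0, limma, no block, leaving out each section in turn, 5 other clusterings, and other definitions of the Lcn2-positive cells. Their kinds were set before the data were examined, with the lower and higher resolutions as 50% and 150% of the main one, so that their values of 0.2 and 0.6 followed from the resolution chosen later. The fit was tested on simulated data of 50 genes in 20 runs. Every simulated gene had the same dispersion (0.0399), effects were exactly additive, and library sizes were held fixed. The rates therefore do not cover gene-specific spread or shifts with the scaling. For 1 week over control, edgeR called 70.0% of genes simulated at 2-fold, 100% at 4-fold and 1.59% of unchanged genes, and DESeq2 called 7.20% of unchanged genes. For mutant over wild type, edgeR called 71.7% at 2-fold and 0.682% of unchanged genes. In simulated cells the sign test found all 20 changed genes one way in every section and 0 of the unchanged ones. That count used the unadjusted p. In the data, 27 genes at the smallest p gave 0 calls after adjustment, so the simulation does not show that changed genes would be called. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and igraph 0.11.9.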

Results

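The data were counts of 50 panel genes in segmented cells of 6 rat kidney sections, with no second section in any group. The wild-type sections held 347622 cells (control), 324796 (1 week of Fe-NTA) and 377793 (3 weeks). The Brca1(L63X/+) sections, called mutant here, held 349164, 425329 and 531476 cells. Panel counts came to 38567196, 38901640 and 29372870 in the wild-type sections and 38596410, 49576385 and 44285350 in the mutant sections, in the order control, 1 week and 3 weeks. The median count per kept cell was 102, 104 and 63 in wild type and 101, 104 and 68 in the mutant, so cells of both 3-week sections were shallower. Fth1, the ferritin heavy chain, took 16.6% of all panel counts, Lrp2 7.41% and Ftl1 6.997%. Every gene passed the background line in every section, but 5 genes were within 5 times the highest single negative probe in at least 1 section: Cdkn2a, S100a8, S100a9, Slc7a11 and Upk3a. The 996 counts of Cdkn2a in the wild-type control section lay below that probe's 1042.

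One week of Fe-NTA against control asked which panel genes differ early in the injured kidney. Lcn2 (ENSRNOG00000013973), an iron-siderophore binding protein released by injured tubules, went from 10.8 to 396 counts per 10000 in wild type, 36.6-fold (95% interval 36.3 to 37.0), and from 19.0 to 299 in the mutant, 15.7-fold (15.6 to 15.9). Mki67, a marker of cycling cells, was 16.4-fold higher in wild type and 8.89-fold higher in the mutant. Bard1, the partner of Brca1, was 6.53-fold and 4.16-fold higher. Brca1 itself (ENSRNOG00000020701) went from 2.80 to 14.8 in wild type and from 3.68 to 15.003 in the mutant, a single Brca1 feature that does not separate the alleles. Amacr, an enzyme of branched-chain fatty acid oxidation, fell to 0.392 of control in wild type and 0.351 in the mutant, and Slc27a2, a fatty acid transporter of the proximal tubule, to 0.371 and 0.390.

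By size, 16 genes were higher and 3 lower at 1 week in wild type, and 15 higher and 3 lower in the mutant. In both genotypes 13 genes were called higher, among them Anxa2, Cdkn1a, Col3a1, Lgals1, Myc and Sting1, and 2 were called lower, Amacr and Slc27a2. On the main scaling the sign was the same in both genotypes for 47 of the 50 genes. The sign of 8 genes in wild type and 6 in the mutant differed between scalings. In the additive fit over both genotypes, edgeR called 29 genes at 1 week, 19 that rose and 10 that fell, with 33 at an unadjusted p under 0.05. The log2 change was 4.65 ± 0.44 (standard error) for Lcn2, adjusted p = 0.00141, and 3.61 ± 0.31 for Mki67. Pink1, a kinase of mitochondrial quality control, changed by -1.03 ± 0.18, adjusted p = 0.00832 by edgeR. Among cell type markers, the edgeR log2 value was -0.82 for Nphs1, which encodes nephrin, -0.84 for Lrp2 and -0.34 for Slc12a1, all called, while Cubn had 0.02 ± 0.20 (adjusted p = 0.906) and Umod -0.58 (adjusted p = 0.0551).

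The count at 1 week depended on single sections and its split on the scaling. It was 17 without the wild-type control section, 8 without wild type at 1 week, 14 without the mutant control and 12 without the mutant at 1 week. The median log2 change of all 50 genes was 0.31 as scaled here, 0.06 with TMM and -0.01 with size factors, and the numbers that rose and fell were 18 and 14 with TMM, 14 and 17 with size factors, 18 and 16 without the 3 top genes in the denominator, 18 and 12 with a fixed cell mix, 19 and 6 per cell and 15 and 18 by DESeq2. None of the 29 genes changed sign under these alternatives.

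**Figure D1:**
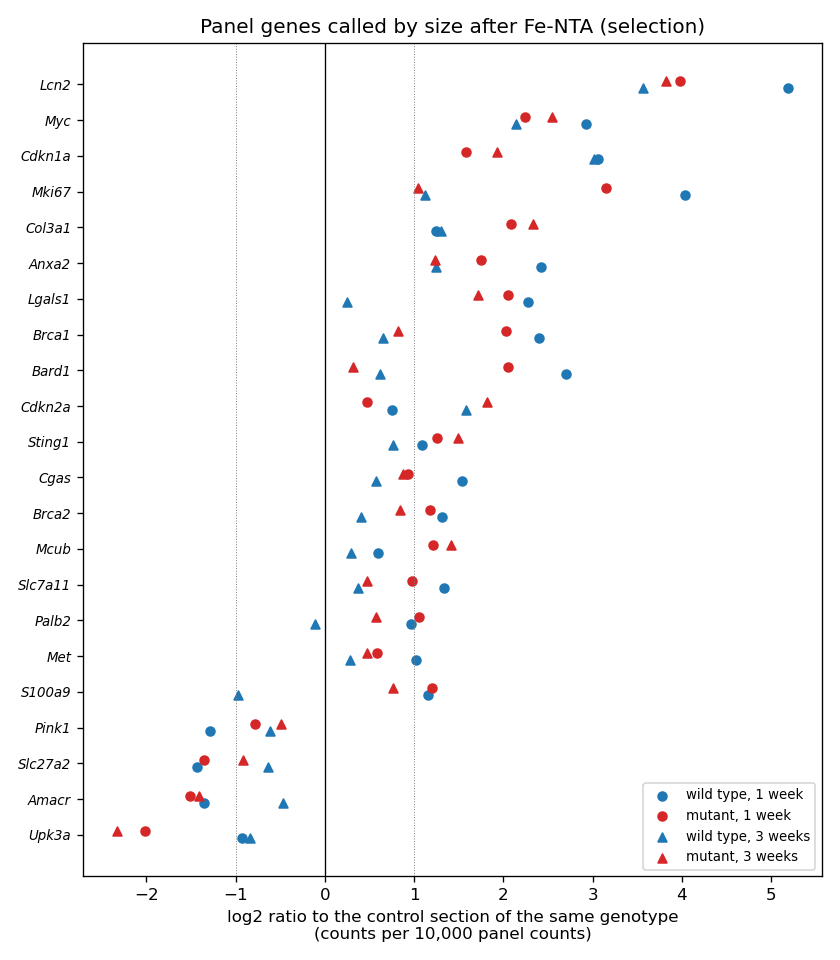
Log2 ratio of each Fe-NTA section to the control section of its genotype (horizontal axis, counts per 10000 panel counts) for a selection of the genes called by size in at least 1 of these comparisons (vertical axis). Circles are 1 week and triangles 3 weeks, blue is wild type and red the mutant, and dotted lines mark 2-fold; Lcn2 lies furthest right, at 5.19 in wild type at 1 week.

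The 3-week sections against control asked which differences were present later in the treatment. Lcn2 stood at 128 counts per 10000 in wild type, 11.8-fold over control (11.7 to 11.9), and at 270 in the mutant, 14.2-fold (14.1 to 14.3). Cdkn1a (ENSRNOG00000000521), the p53 target p21 that arrests the cell cycle, was 8.08-fold higher in wild type and 3.81-fold in the mutant, and Myc, a growth-promoting transcription factor, 4.41-fold and 5.82-fold. Col3a1, a fibrillar collagen, was 2.46-fold higher in wild type and 5.05-fold in the mutant. Mki67 was 2.17-fold and 2.07-fold higher, at 24.2 and 35.7 counts per 10000. Cdkn2a, which encodes the cell cycle inhibitor p16, was 2.98-fold and 3.51-fold higher, at counts close to the negative probes.

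By size, 7 genes were higher and 0 lower at 3 weeks in wild type, and 10 higher and 3 lower in the mutant; per kept cell 14 genes were called in wild type. All 7 wild-type genes were also called in the mutant: Anxa2, Cdkn1a, Cdkn2a, Col3a1, Lcn2, Mki67 and Myc. The genes called lower in the mutant included Amacr and Upk3a. On the main scaling 42 of the 50 genes had the same sign in both genotypes, but the sign of 16 genes in wild type and 9 in the mutant differed between scalings. edgeR called 13 genes at 3 weeks, 8 that rose and 5 that fell, with 23 at an unadjusted p under 0.05. The genes that rose included Myc at a log2 change of 2.36 ± 0.31 (adjusted p = 0.0119), Cdkn1a at 2.41 ± 0.39 and Sting1, the adaptor of cytosolic DNA sensing, at 1.13 ± 0.25 (adjusted p = 0.0250). Those that fell included Ftl1, Nphs1, Slc27a2 and Tfrc.

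This count was 7 without the mutant control, 7 without either 1-week section taken singly, and 24 without wild type at 3 weeks. The median log2 change of all genes at 3 weeks was 0.21 as scaled here and -0.24 per kept cell, where 5 genes rose and 17 fell. The split was 7 and 8 with size factors, 8 and 9 by DESeq2, 13 and 7 with TMM and 6 and 3 with a fixed cell mix, and no called gene changed sign.

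Mki67, Bard1 and Brca1 were called lower by size at 3 weeks than at 1 week in both genotypes. Mki67 at 3 weeks was 0.132 of its 1-week level in wild type and 0.232 in the mutant, Bard1 0.236 and 0.3003, and Brca1 0.298 and 0.433. Wild type had 0 genes called higher and 10 lower, which also included Anxa2, Lcn2, Lgals1, Palb2, S100a8 and S100a9, and per kept cell 17 genes were called. In the mutant 1 gene was higher, Cdkn2a at 2.52-fold, and 4 were lower. No test was run on these pairs of single sections.

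**Figure D2:**
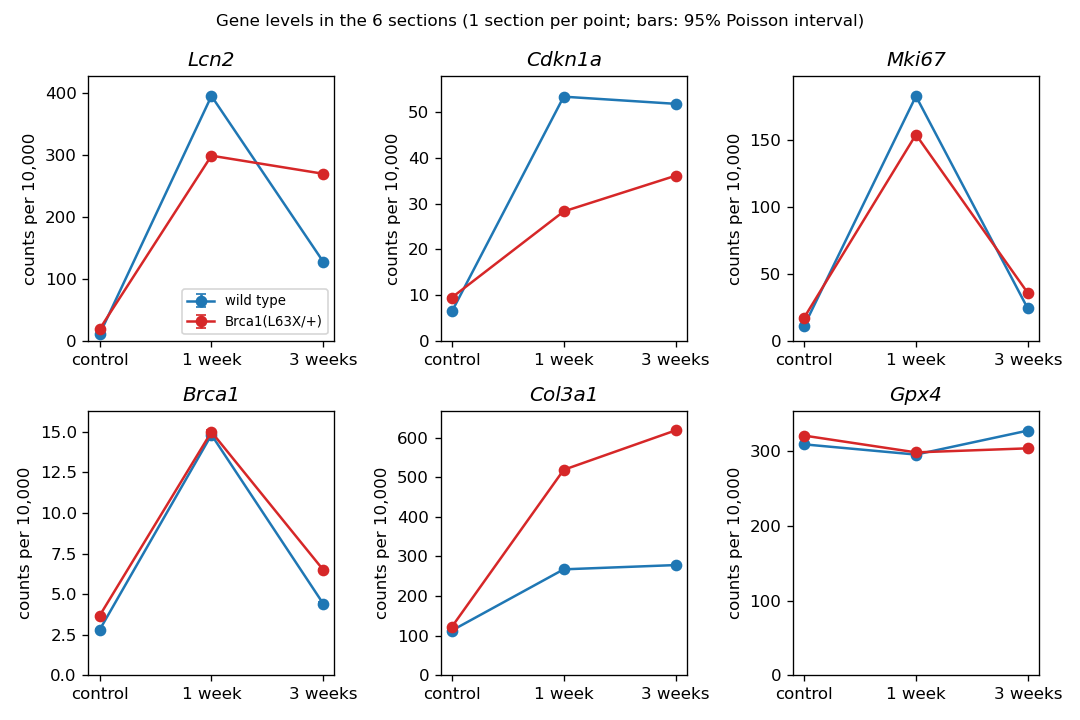
Counts per 10000 panel counts (vertical axes, from 0) of Lcn2, Cdkn1a, Mki67, Brca1, Col3a1 and Gpx4 in the control, 1-week and 3-week sections (horizontal axes). Each point is 1 section, blue for wild type and red for Brca1(L63X/+), and bars are 95% Poisson intervals, mostly smaller than the points; Mki67 is highest at 1 week in both genotypes, and Gpx4 lies between 296 and 328 in all sections.

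Among the ferroptosis and iron genes of the panel, Lcn2 had the largest change in edgeR at both times. Gpx4 (ENSRNOG00000013604), which reduces lipid peroxides, stood at 309, 296 and 328 counts per 10000 in wild type and 321, 299 and 304 in the mutant, with an edgeR log2 value of -0.09 ± 0.14 at 1 week (adjusted p = 0.581) and 0.00 ± 0.14 at 3 weeks. Slc7a11, the cystine importer, rose at 1 week by a log2 change of 1.16 ± 0.28 (edgeR adjusted p = 0.0198), from 1.31 to 3.31 in wild type and from 1.998 to 3.94 in the mutant, and at 3 weeks its value was 0.43 ± 0.28 (adjusted p = 0.258). Of the 2 promotion genes, Tfrc, the transferrin receptor, fell at 3 weeks by a log2 change of -0.97 ± 0.18 (edgeR adjusted p = 0.0206), while Ncoa4, the ferritin cargo receptor, had 0.37 ± 0.17 (adjusted p = 0.132). Adjusted over the list alone, the counts were again 1 of 2 for defence at 1 week and 1 of 2 for promotion at 3 weeks, with 0 for defence at 3 weeks and 0 for promotion at 1 week.

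Of the 9 iron handling genes, 3 rose at 1 week and 0 fell: Lcn2, and the iron chaperones Pcbp1 at a log2 change of 0.41 ± 0.12 and Pcbp2 at 0.45 ± 0.10. Neither chaperone passed with TMM (0.15 ± 0.25 and 0.20 ± 0.24) or with size factors (0.09 ± 0.14 and 0.13 ± 0.11), nor by DESeq2 or limma. Adjusted over the list alone, 2 rose. At 3 weeks Lcn2 rose, and Tfrc and the ferritin light chain Ftl1 (-0.49 ± 0.11, edgeR adjusted p = 0.0250) fell, the same numbers as when adjusted over the list alone. Fth1 had -0.11 ± 0.04 at 1 week and -0.06 ± 0.04 at 3 weeks, the importer Slc11a2 0.30 ± 0.17 and 0.10 ± 0.17, and the exporter Slc40a1 0.05 ± 0.18 and 0.14 ± 0.18, all outside the edgeR threshold. The mean over genotypes of the iron list's median log2 ratio changed sign with the scaling, to -0.14 with TMM and -0.20 with size factors at 1 week and to -0.32 per cell at 3 weeks.

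Among 8 genes of DNA damage response and arrest, 6 rose at 1 week and 0 fell in edgeR, and adjusted over the list alone the numbers were the same. They included Bard1, Cdkn1a, Brca1, Brca2 at 1.25 ± 0.25 and Palb2 at 1.01 ± 0.26. At 3 weeks 2 rose, Cdkn1a and Cdkn2a, also when adjusted over the list alone, while Brca1 had 0.74 ± 0.23 (edgeR adjusted p = 0.0659). Of 8 carcinogenesis genes, 4 rose at 1 week (Brca1, Brca2, Met and Myc) and 1 fell (Vegfa, -0.49 ± 0.16), and 2 rose at 3 weeks (Cdkn2a and Myc), with no difference when adjusted over the list alone. Both injury genes, Anxa2 and Lcn2, rose at both times, also when adjusted over the list alone. Mki67 for the cell cycle and Col3a1 for inflammation and fibrosis rose at both times as well. Each of these is the only panel member of its list, so the list alone gives no adjustment. Pink1, also the only panel member of its list, mitochondria, fell at 1 week. Its 3-week change of -0.55 ± 0.18 did not pass (edgeR adjusted p = 0.0659). Over the list alone it passed, but only at the unadjusted edgeR p of 0.0237.

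Mutant against wild type asked whether the heterozygous Brca1 change alters the levels of these genes. At 3 weeks Lgals1, a galectin expressed by stromal cells, was 3.59-fold higher in the mutant (95% interval 3.56 to 3.61), Col3a1 2.22-fold (2.22 to 2.23), Sting1 2.20-fold and Lcn2 2.11-fold. Umod, made by the thick ascending limb, was at 0.483 of wild type there, and Slc12a3, the transporter of the distal convoluted tubule, at 0.494. In control sections Upk3a, a urothelial gene, was the 1 gene called, 3.01-fold higher at 2.37 counts per 10000. Brca1 stood at 3.68 in the mutant and 2.80 in the wild-type control section, 15.003 and 14.8 at 1 week, and 6.50 and 4.41 at 3 weeks.

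By size, 1 gene was higher and 0 lower in control sections, 0 differed at 1 week, and 6 were higher and 2 lower at 3 weeks, where the others were the low-count S100a8 and S100a9. Across conditions edgeR called 0 of 50 genes, with 4 at an unadjusted p under 0.05: Col3a1 (log2 0.74 ± 0.23), Slc22a17, Sting1 and Umod (-0.61 ± 0.16), all with adjusted p = 0.289. DESeq2 called 0 genes with 6 unadjusted, and limma 0 with 7. The functional lists gave 0 genes each. Over the list alone 1 gene passed, Col3a1, but it is the only panel member of its list, so its p there is the unadjusted one. Without the wild-type control section edgeR called 4 genes, Col3a1 at 1.05, Lgals1 at 0.995, Lrp2 at -0.47 and Umod at -0.82. Without the mutant control the same 4 Fe-NTA sections estimate genotype, so that fit, with the same 4 genes, is no separate result.

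The difference between the genotypes' responses was not tested week by week. With both weeks joined in a term chosen after the data were seen, edgeR called 0 of 50 genes, with 3 at an unadjusted p under 0.05: Cdkn1a (-1.28 ± 0.59), Col3a1 (0.94 ± 0.36) and Umod (-0.61 ± 0.23). In that fit limma called 0 with 2 unadjusted, and DESeq2, with 10 unadjusted, called 5: Aqp2, Atp6v0d2, Cdkn1a, Col3a1 and Upk3a. The mutant minus wild-type difference of log2 ratios to control was -1.48 for Cdkn1a and -1.22 for Lcn2 at 1 week, and 1.47 for Lgals1, 1.04 for Col3a1 and -1.08 for Cdkn1a at 3 weeks. It did not keep its sign for Lcn2 (0.26 at 3 weeks) or Lgals1 (-0.22 at 1 week). At 1 week 0 genes met the rule for opposite responses. At 3 weeks 1 gene met it, S100a9, a neutrophil gene, with -0.97 in wild type and 0.76 in the mutant at 0.710 and 1.85 counts per 10000.

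Cell clusters were compared to see which cell types the changes accompanied. Proximal tubule-like cells, led by Cubn, Slc27a2, Lrp2 and Amacr, made up 37.8%, 24.8% and 31.6% of kept cells in wild type and 34.9%, 23.2% and 23.1% in the mutant (control, 1 week, 3 weeks). The class joins clusters 2 and 3, whose mix differed: in the same order cluster 2 held 20.2%, 14.5% and 16.0% in wild type and 18.8%, 18.8% and 17.7% in the mutant, and cluster 3 17.6%, 10.2% and 15.6%, and 16.0%, 4.42% and 5.38%. Umod, a clustering gene, was found in 36.3% of the cells of cluster 2 and 99.98% of those of cluster 3, and fits within the class compare different mixes. The limma log2 odds ratio was -0.86 ± 0.18 at 1 week (adjusted p = 0.0187) and -0.62 ± 0.18 at 3 weeks (adjusted p = 0.0373), but it missed the threshold in 4 of 5 other clusterings, at values between -0.33 and -0.48 at 1 week. The share of podocyte-like cells, with Nphs1 among their leading genes, fell from 3.68% to 1.84% in wild type and from 3.54% to 1.85% in the mutant at 3 weeks (log2 odds ratio -0.997 ± 0.115, limma adjusted p = 0.00367), while their 1-week value of -0.45 lost its call in 4 clusterings. A share can fall without loss of cells, where other cells are added or a section covers other tissue. In the mutant, proximal tubule-like cells numbered 120823 in control and 121511 at 3 weeks, and podocyte-like cells 12277 and 9738. Cluster 7, led by Cdkn2a, Lcn2, Cdkn1a, Myc and Mki67, held 1.35% and 1.73% of control cells against 10.8% and 10.3% at 1 week (log2 odds ratio 2.92 ± 0.19, limma adjusted p = 0.00153). Cluster 7 was not stable. Of the cells in it or in its nearest match, 29.7% were in both under another seed and 18.2% with a minimum of 20 counts. With that minimum the call was lost. For genotype, limma passed 0 of 13 sets, with 3 at an unadjusted p under 0.05: clusters 0, 6 and 12. In other clusterings, numbered on their own, sets passed as higher in the mutant. Cluster 0, the cells without clustering genes, passed at lower resolution (limma adjusted p = 0.000291) and with another seed (limma adjusted p = 0.0289). It holds the same cells there as in the main clustering, with the same log2 odds ratio of 1.10 (main limma adjusted p = 0.144). Only the spread borrowed from the other sets and the adjustment differ, so these 2 calls are no separate support. With a minimum of 20 counts cluster 0 had 1.47 (limma adjusted p = 0.0180). The others that passed were cluster 7 at lower resolution (0.81), cluster 8 with another seed (1.92) and clusters 8 and 12 with a minimum of 20 (1.06 and 1.05). None passed at higher resolution or on all panel genes.

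Cluster 7 had a log2 odds ratio of 2.58 ± 0.19 at 3 weeks, and 6 further sets passed the limma threshold there. Clusters 10 and 13, both led by Col3a1, rose by log2 odds ratios of 1.29 ± 0.23 and 1.38 ± 0.27, cluster 6, led by Plvap, by 0.88 ± 0.25, cluster 12, led by Lcn2 and Col3a1, by 3.25 ± 0.39, and the cells without clustering genes by 2.90 ± 0.30. At 1 week clusters 10 and 13 had 0.27 and 0.44 (limma adjusted p = 0.398 and 0.259). Cells of clusters 10, 12 and 13 held a median of only 3, 3 and 2 counts of the clustering genes. Cells of both 3-week sections were shallower, and whether depth accounts for these rises was not tested. Cluster 11, a shallower cluster led by Amacr and Slc27a2, had -0.77 ± 0.12. Cluster 1, led by the thick ascending limb genes Slc12a1 and Umod, had -0.09 ± 0.13 at 1 week (limma adjusted p = 0.631).

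**Figure D3:**
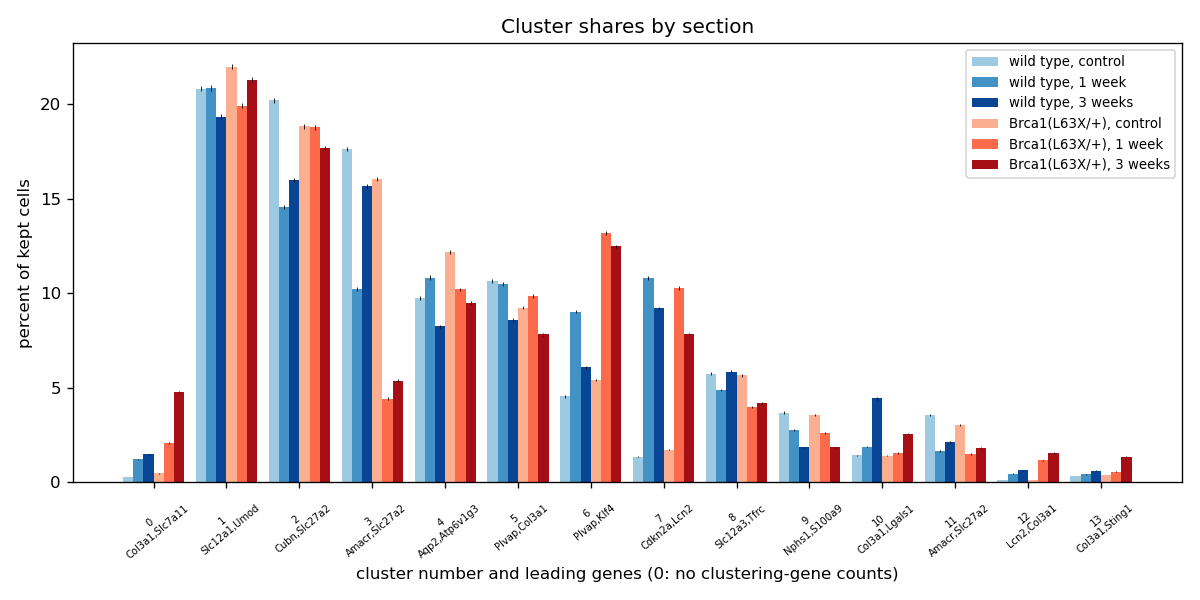
Percent of kept cells (vertical axis, from 0) in each cluster (horizontal axis, with leading genes; cluster 0 holds cells without a count of the clustering genes) in the 6 sections. Blue bars are wild type, red bars Brca1(L63X/+), darker with time, and bars carry 95% Clopper-Pearson intervals; cluster 7 holds 1.35% and 1.73% of control cells and 7.84% to 10.8% after Fe-NTA.

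Within proximal tubule-like cells, of 34 genes not used for clustering, edgeR called 23 that rose and 4 that fell at 1 week, and 19 and 4 at 3 weeks. Lcn2 rose by a log2 change of 6.58 ± 0.47 at 1 week (adjusted p = 2.34e-05) and 5.85 ± 0.45 at 3 weeks. Cdkn1a rose by 3.76 ± 0.41 and 4.10 ± 0.41, Anxa2 by 3.64 ± 0.27 and 2.95 ± 0.26, and Brca1 by 2.68 ± 0.29 and 1.34 ± 0.28 (edgeR adjusted p = 0.00435 at 3 weeks). The 4 genes that fell at both times were Amacr, Fth1, Ftl1 and Pink1, and Gpx4 had 0.12 ± 0.15 and 0.19 ± 0.15. For genotype edgeR called 0 genes with 0 at an unadjusted p under 0.05, while DESeq2 called 1, Cdkn2a at 0.69 ± 0.21. In the single clusters edgeR called Cdkn2a in cluster 3 (1.07 ± 0.20) and Col3a1 in cluster 10 (0.47 ± 0.09) as higher in the mutant. The 3-week count was 14 per cell, 12 without either control section taken singly and 9 without the mutant at 3 weeks. Segmented cells can hold transcripts of their neighbours, so Col3a1 in this class is not shown to be made by tubule cells.

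Proximal tubule-like cells with at least 2 Lcn2 counts were compared with the other cells of the class to describe the injured state. They made up 0.463%, 54.3% and 24.97% of these cells in wild type and 1.07%, 48.3% and 44.7% in the mutant, without thinning. After thinning to 20 counts, Lcn2 was found in 38.2% and 19.3% of the class at 1 and 3 weeks in wild type and in 33.5% and 33.7% in the mutant, so that at equal depth the mutant's share was not lower at 3 weeks. Met, the receptor of hepatocyte growth factor, was 3.01-fold higher in the Lcn2-positive cells, Cdkn2a 2.56-fold, Sfxn3 2.45-fold, Myc 2.29-fold, Anxa2 2.27-fold, Cdkn1a 2.05-fold and Brca1 2.01-fold, each higher in 6 of 6 sections. The control sections held only 602 (wild type) and 1296 (mutant) Lcn2-positive cells, each thinned to 20 counts. For low-count genes the sign there can rest on very few transcripts. This holds above all for Cdkn2a, which over all kept cells of the wild-type control section was 0.952 times the highest negative probe. Segmented cells can also hold transcripts of their neighbours. Sfxn3 was a leading gene of clusters 1 and 8, outside this class. In the control sections 2.14% (wild type) and 3.79% (mutant) of all kept cells had at least 2 Lcn2 counts, more than in this class. How far the Lcn2-positive cells are mixed with neighbours was not tested. Amacr was 2.13-fold lower, in 6 of 6 sections, and Pink1 1.56-fold lower. By the exact sign test 0 of 49 genes passed, with 27 at the smallest possible p of 0.031, adjusted p = 0.0567. With 1 count as the limit, or without thinning, 31 genes reached that p and all 31 passed at an adjusted p = 0.0494 (exact sign test); over all definitions tried, the smallest adjusted p ran from 0.0494 to 0.109.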

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

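The test of transcripts per kept cell was chosen after the result was seen, and so were the limits by which the intervals of the codeword ratios were read. S100a9, a neutrophil gene, went opposite ways at 3 weeks: its mutant minus wild-type difference of log2 ratios to control was 1.73, with -0.97 in wild type and 0.76 in the mutant. The difference was not tested at 3 weeks alone, and with both weeks joined edgeR gave 0.88 ± 1.07 (adjusted p = 0.952), a test also chosen after the result was seen. Its counts lay within 5 times the highest negative probe in 2 sections, and per cell, with TMM and with size factors one genotype's change was below 1.5-fold, so that 0 genes met the rule there.

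A decoded barcode assigned to no gene, UnassignedCodeword_0336, appeared above its control level in every Fe-NTA section. It had 25 and 26 counts in the wild-type and mutant control sections, 1082 and 610 at 1 week and 372 and 602 at 3 weeks, and the lowest Fe-NTA rate was 18.3-fold over the highest control rate. Lcn2 was the gene most raised in the cells that held it in each of the 6 sections, and 93.3% to 98.8% of such cells in Fe-NTA sections held Lcn2. For miscalled Lcn2 transcripts a rate per Lcn2 count within 2-fold was predicted between cells with 20 or more and cells with 1 to 5 Lcn2 counts, and a ratio of at least 3 was the bound against them. The smallest ratio was 3.31 (95% interval 2.52 to 4.42), all 4 point values met that bound, and all 4 intervals lay above 2, which argues against miscalling at a constant rate, but only 1 interval lay wholly above 3, so miscalling that grows with Lcn2 density, which was not tested, and another transcript cannot be told apart.

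Amacr and Pink1 were lower at 1 week in both genotypes. Fewer proximal tubule-like cells would leave their level within clusters 2 and 3 near control, but the value nearest to 0 there was -0.634 on the log2 scale. A larger share of counts taken by other genes would leave transcripts per cell near control, but the value nearest to 0 was -0.717. That value is over all kept cells, where the proximal tubule-like share also fell. Within clusters 2 and 3 the log2 change of the median count per cell at 1 week lay between -0.17 and -0.01. The tests argue against each of these alone as the whole cause. The 2 acting together would leave transcripts per cell near control within clusters 2 and 3. There the median count per cell did not rise, while both genes' shares fell by 0.634 or more. These values argue against the combination for these 2 genes, although transcripts per cell were not computed within the clusters. Lower levels per proximal tubule-like cell remain a hypothesis. Amacr was lower in both genotypes in 14 of 14 clusters, including those of other cell types, and whether spilled transcripts or expression in those cells accounts for this was not tested; Pink1 was not lower in mutant cells of the podocyte-like cluster 9 (0.12).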

How the results depend on the processing

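Calls by size moved mainly with the fold limit. At 1.5-fold, 30 genes were called at 1 week in each genotype, 22 in wild type and 26 in the mutant at 3 weeks, 23 in wild type between 3 weeks and 1 week, and 5, 3 and 20 between genotypes in control, 1-week and 3-week sections. At 3-fold the counts were 9 and 10 at 1 week, 3 and 7 at 3 weeks, 3 in the mutant between 3 weeks and 1 week, and 1 between genotypes at 3 weeks; a lower or higher limit by construction gives more or fewer. Per cell, 14 genes were called in wild type at 3 weeks and 17 between 3 weeks and 1 week, and with size factors 1 between genotypes at 1 week. Per cell, with TMM and with size factors 0 genes went opposite ways.

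The edgeR count at 3 weeks was 22 per cell and 20 with TMM. Leaving out 1 section at a time gave 8 to 35 genes at 1 week, 7 to 24 at 3 weeks and 0 to 4 for genotype, each with 1 residual degree of freedom. Of the 348 values of the 29 genes called at 1 week under the other alternatives, 316 kept their call and 32 lost it with the sign kept. At 3 weeks 140 kept it and 16 lost it. With 1 section left out, a larger part of the values lost the call at both times. The filter on genes above background removed no gene and so gave no values. For the difference between genotypes' responses with both weeks joined, chosen after the data were seen, edgeR called 0 genes with 3 unadjusted, also 0 per cell, with TMM and with size factors, limma 0 and DESeq2 5. No paired analysis was possible because the labels pair no sections.

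The iron handling list's median log2 ratio, averaged over genotypes, was 0.21 per cell, -0.14 with TMM, -0.20 with size factors and -0.032 without the 3 top genes at 1 week, and -0.32, 0.046, -0.056 and 0.011 at 3 weeks. Its calls at 3 weeks over both genotypes were 5 per cell, and 4 with size factors, without the 3 top genes and at 1.5-fold. For DNA damage response at 3 weeks the median was 0.26 per cell, 0.53 with size factors, 0.60 without the 3 top genes and 0.54 with a fixed cell mix, with 10 calls at 1.5-fold, and at 1 week 7 calls at 3-fold. For carcinogenesis the median was 0.45 with TMM and 0.39 with size factors at 1 week and 0.14 per cell at 3 weeks, with 4 calls at 3-fold at 1 week and 8 at 1.5-fold at 3 weeks.

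The lower share of proximal tubule-like cells kept its sign but lost its call when clustered on all panel genes, at lower resolution, with another seed and with a minimum of 20 counts: log2 odds ratios of -0.35, -0.48, -0.33 and -0.40 at 1 week and -0.38, -0.34, -0.18 and -0.17 at 3 weeks. Podocyte-like cells at 1 week had -0.52, -0.46, -0.49 and -0.48 at lower and higher resolution, another seed and a minimum of 20. Cluster 7 with a minimum of 20 counts had 0.47 and 0.40 at 1 and 3 weeks. Within proximal tubule-like cells, 14 genes passed at 3 weeks per cell, 9 to 23 with 1 section left out, and DESeq2 called 1 for genotype. For Lcn2-positive cells 31 genes passed with a limit of 1 count and 31 without thinning, since more genes reached the smallest p. In all kept cells 3 genes reversed: Klf4 at -0.12, Lrp2 at 0.28 and Sting1 at -0.28. Unless stated, the cause was not tested. Cdkn2a, S100a8, S100a9, Slc7a11 and Upk3a are limited by their closeness to the highest negative probe. In the shallowest section, 59.8% of kept cells reached 50 counts.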

Other observations

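The test of other splits of the sections was chosen after the result was seen. Within each section, cells with an Mki67 count had more Brca1 (3.01 to 4.12-fold), Brca2 (1.65 to 2.30-fold) and Bard1 (3.61 to 5.46-fold) per panel count than cells without. In cells without an Mki67 count, the log2 ratio of 1 week to control in wild type and mutant was 1.20 and 1.10 for Brca1, 0.63 and 0.73 for Brca2 and 1.23 and 0.97 for Bard1; these cells were not thinned, so cycling cells are not excluded. Cells of cluster 7 at 1 week had Mki67 in 41.3% of wild-type and 21.8% of mutant cells after thinning to 20 counts, against 4.35% and 6.09% of the cluster's cells in the control sections. Over all kept cells the thinned values were 23.9% and 18.9% at 1 week against 2.03% and 3.05% in control, so the rise was not particular to cluster 7.

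Cdkn1a and Mki67, a gene of arrest and a gene of cycling, were found in the same segmented cell 1.14 to 1.56 times as often as independent detection would give over the 6 sections. These cells were not thinned, so depth adds to that ratio.

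Col3a1 and Lgals1 were higher in the mutant Fe-NTA sections, by log2 ratios of 0.96 and 0.15 at 1 week and 1.15 and 1.84 at 3 weeks, against 0.11 and 0.37 in the control sections, so that Lgals1 at 1 week did not exceed its control ratio. With a fixed cluster mix, more cells of the Col3a1-led clusters would leave under 50% of these values. The smallest share left was 84.4%, for Col3a1 at 3 weeks. This argues against more cells assigned to those clusters, but it cannot exclude more stromal tissue. The clusters were made without stromal genes and may hold unresolved stromal cells, and segmented cells can hold transcripts of their neighbours. At 3 weeks the mutant minus wild-type difference of Col3a1 log2 ratios to control was 1.23, 0.71 and 1.49 in clusters 1, 2 and 4. It was 0.07, 0.20 and 0.43 in the Col3a1-led clusters 0, 10 and 13. With 1 section per genotype and condition, a difference between single animals or sections and a genotype effect cannot be told apart. Across the 50 genes, the real split of the 6 sections into 3 and 3 gave 0 genes, the highest other split gave 2, and 10 splits are too few for a share under 0.05; at least 0 genes in 10 of 10 splits holds by construction.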
